A study of Homo sapiens and Mus musculus with 11 samples.

How the data were processed

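MeRIP-Seq sequences RNA fragments pulled down with an antibody against N6-methyladenosine (m6A), a methylated adenosine in RNA, beside fragments of the same RNA that were not pulled down (input). Per the labels, total RNA of adult C57BL/6 mouse whole brain was depleted of ribosomal RNA and passed through 2 rounds of pull-down. The labels describe 11 samples. The 5 brain samples are 3 MeRIP and 2 input libraries, and the 6 HEK293T samples are 3 MeRIP and 3 input libraries. HEK293T is a human embryonic kidney cell line. The titles name SYSY as the antibody source for 2 brain MeRIP libraries and NEB for 1, while the vendor label gives Synaptic Systems for all. The HEK293T samples were not analysed here.

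The one deposited table lists regions enriched in brain MeRIP over control, 1 region per line, with mouse RefSeq gene models. The submitters' processing notes name BWA, SAMtools, bedtools and the builds mm9 and hg19, without roles or versions. Coordinates are given as in the table and were taken as mm9, the mouse build among these. The region caller, its thresholds and the libraries that entered each column are not given in the sources used here.

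The authors' coverage of each region in MeRIP and in control is a signal with 1 pooled value each, per the file headers, whose normalization is not given. Its depth is therefore unknown, and no interval from counting could be set. The authors' q-value per region is part of the deposited table, and its test is not given. The authors' enrichment score (the deposited ratio column) has an unstated scale. Across regions it followed the log2 of the coverage ratio (Pearson r 0.857) with a mean difference of 0.40 on that scale. A second deposited score equals the negative log10 of q times that ratio in all 2487 regions (tolerance 0.001). The q-value never rose as the ratio column rose. The summary line of the authors' deposited table counts 2570 regions, 83 more than analysed here, and 448 intergenic ones against 378 here. The deposited centre position lies below the midpoint in all 2487 regions, at a median of 16.8% of the width. The deposited lengths of 5' and 3' UTRs follow the chromosome's direction rather than the gene's strand and were not used.

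From these values the coverage ratio (MeRIP over control, log2 where stated) was computed per region, without a pseudocount. Each midpoint was placed in the transcript of its row as 5' UTR, coding sequence, 3' UTR, intron or intergenic, and the distance from the stop codon was counted in transcript bases. Outside genes thus means outside the coding gene model of the row, and noncoding genes were not considered. Observed positions were set against 1000 random placements of the same number of midpoints along the same transcripts, giving two-sided permutation p-values of at least 0.002. The authors' class flags matched for 897 of 899 midpoints in 3' UTRs and 1108 of 1108 in coding sequence.

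Gene lists were fixed before the data were examined. They cover m6A enzymes and readers, receptors, channels, synaptic proteins, cell type markers, housekeeping complexes, transcription and chromatin factors, clock genes, Wnt and Notch signalling, axon guidance and 5 symbol families (Olfr, Krt, Zfp, Slc and Pcdh). A gene listed under 2 symbols was counted once. Members were matched by symbol, and an added alternative also matched older symbols through the synonyms of human genes, which found 1 more member. Mouse names that are not among those synonyms would be missed. A list member carried a region if a midpoint lay inside its gene model by the authors' flag. The planned background was all genes of the organism. No mouse gene table was used here, so each list of at least 5 members was compared with the other members of the lists (669 symbols in all) by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over 26 lists. Human protein-coding symbols (assembly GRCh38.p14, names only) served as another background, to which 83.4% of the 1830 genes with a region matched. The gene models were all of coding transcripts, so the lists of 26 long noncoding RNAs (with Malat1) and 15 mitochondrial genes were not searched. List medians of the strongest log2 coverage ratio per gene were set against 100000 random lists of the same size drawn from all genes with a region.

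Named genes followed a rule fixed beforehand. It takes the 10 genes with the highest coverage ratio inside a gene, the 10 with the most regions (ties by highest ratio), up to 4 members of each list with the highest ratio and up to 2 without a region, and the m6A enzymes and readers in full. Predicted genes were counted and not named, and some genes that the rule takes are not reported here. Tests per library, a comparison of antibodies and a comparison of replicates needed values per library and were not run. Regions and genes are not replicates, so p-values over them describe these pooled libraries. Alternatives covered stricter subsets of regions, other reference points, other placements, other backgrounds and 2 regions per gene. Some tests were changed after a result had been seen. The bound of the gene-model test of the strand difference was replaced after a first bound had left it undecided. A shift test with the centre position was replaced by one on internal exons, because a reference point far enough to the left turns the sign by construction (for the median distances, at 40% of the width). The second long-exon test and the placement in long exons followed the first long-exon result. The Zfp test was first run as a test of an explanation and is given as values. A comparison of enrichment near the stop codon with that elsewhere was computed and left out, since no alternatives were run for it. The code was tested on simulated data. Over the 2046 exonic midpoints, even placement returned an observed over expected ratio of 1.04 at the stop codon, and moving 20% of them to it returned 2.56. A list raised to 60% of its members was found in 99 of 100 simulated sets, with 2 false calls among 1900 unchanged lists. Of the lists called higher below, only potassium channels reached such a share. The others lay between 38.5% and 45.5%, so this recovery does not carry over to them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.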

Results

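m6A was mapped in adult mouse brain RNA by MeRIP-Seq, and the comparison asks where in the transcriptome antibody pull-down enriched fragments over input. The labels give 3 brain MeRIP and 2 brain input libraries. By their titles these come from 2 brain RNA samples, and sample 2 has a MeRIP library of each antibody source. The table holds 1 pooled coverage value for each of the 2 groups per region, so values carry no replicate error, and depth is unknown. It listed 2487 regions on 21 chromosomes, of which 65 lay on X and 1 on the mitochondrial chromosome. Coordinates are those of the table, taken as mm9.

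The highest coverage ratio inside a gene belonged to Rtn4r, which encodes the Nogo receptor of axon growth inhibition, at 50.04 (NM_022982, chromosome 16, 18151650 to 18152349, coding sequence; MeRIP coverage 1401, control 28). Foxk1, a forkhead transcription factor gene, followed at 48.6 in its 3' UTR (NM_199068, chromosome 5, 142933050 to 142933449). Lrrc4b, a leucine-rich repeat synaptic adhesion gene, reached 47.2 with a midpoint 20.5 bases after its stop codon (NM_198250, chromosome 7, 51718050 to 51718399). The potassium channel gene Kcnh1 reached 44.5 in its 3' UTR (NM_001038607, chromosome 1, 194330250 to 194330799).

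The other 6 of the 10 genes with the highest ratios had regions in coding sequence, both UTRs and an intron. Ugcgl1, whose product glucosylates misfolded glycoproteins, had a ratio of 47.3 in an intron (NM_198899, chromosome 1, 36200900 to 36201299). The sialyltransferase gene St3gal2 had 46.6 in its 5' UTR (NM_009179, chromosome 8, 113481100 to 113481599), and Rbbp6 had 43.4 in its 5' UTR (NM_175023, chromosome 7, 130113900 to 130114349). Rps19bp1 had 46.2 in its 3' UTR (NM_175109, chromosome 15, 80091050 to 80091599). The mitochondrial methionyl-tRNA synthetase gene Mars2 had 44.2 in coding sequence (NM_175439, chromosome 1, 55294900 to 55296049), and the membrane metalloproteinase gene Mmp16 had 43.6 in coding sequence (NM_019724, chromosome 4, 18043000 to 18043499). Control coverage lay below the median over all regions (31.2) in these 10 genes, from 9.25 in Ugcgl1 to 30.5 in St3gal2.

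Across all regions the median coverage ratio was 16.3 (log2 4.02), with a range of 8.47 to 50.04. Median width was 500 bases, from 350 to 38600. In the authors' deposited table only 2 regions had a q as low as 0.05, those of Mars2 and of the ephrin gene Efnb2 (NM_010111, chromosome 8, 8620350 to 8620849, coding sequence), 30 had q at most 0.1, and 1183 (47.6%) had a q of 1. These 2 genes were named after their q had been seen. With q below 1 required, 1304 regions remained.

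Regions inside genes numbered 2109 (84.8%) and fell in 1830 genes. Most of these genes, 1574, carried 1 region, 237 carried 2 and 19 carried 3 or more. Spen, a transcriptional corepressor gene, carried 4 (2 in coding sequence, 1 in an intron and 1 in the 3' UTR), and the sodium channel gene Scn8a carried 4. Nsd1, a histone methyltransferase gene, Dido1 and Slitrk3, a synaptic leucine-rich repeat gene, carried 3 each, all in coding sequence. Zkscan1 carried 3 in its 3' UTR. Smcr8, Zcchc14 and the neuroligin gene Nlgn1 also carried 3 each. With q below 1 required, Spen, Scn8a, Dido1, Slitrk3, Zkscan1, Smcr8 and Zcchc14 each lost at least 1 of these regions.

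Region midpoints gathered at stop codons, the position the series title names together with 3' UTRs. Of 2046 midpoints in exons, 706 (34.5%) lay within 200 bases of the stop codon, against 237 (11.6%) under random placement in the same transcripts. The observed number was 2.99 times the expected one (two-sided permutation p = 0.002, the smallest that 1000 placements can give). The 100 bases before the stop codon held 195 midpoints (60.2 expected), the first 100 after it 177 (58.2 expected) and the next 100 after it 192 (56.5 expected). Efnb2 (12.5 bases before the stop codon), Shank2 (10.5 after), Setd5 (11.5 after) and Htr2a (28.5 before) are examples, chosen after their distances were seen. The median distance was -63 bases, with quartiles of -581 and 208.

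**Figure D1:**
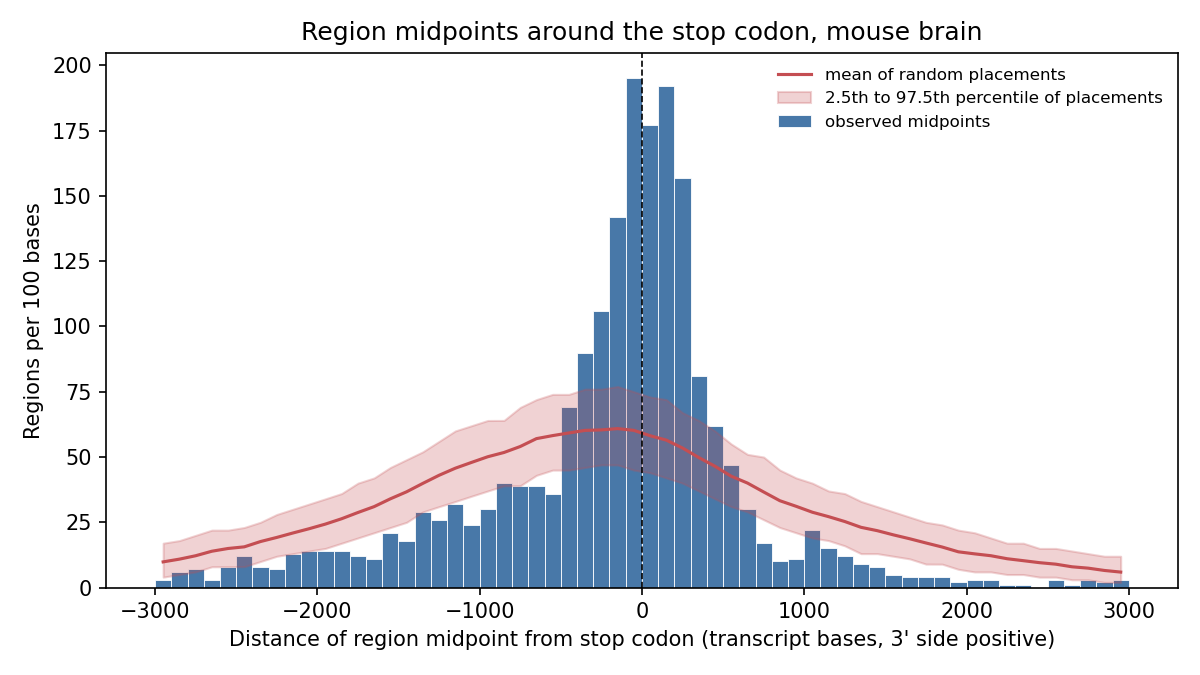
Distance of each of the 2046 exonic midpoints from the stop codon of its transcript (horizontal axis, transcript bases, 3' side positive) against the number of regions per 100 bases (bars). The line and band show the mean and the central 95% of 1000 random placements, and the bars from 100 bases before to 200 after the stop codon reach 195, 177 and 192.

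By class, 1108 midpoints (44.6%) lay in coding sequence and 899 (36.1%) in 3' UTRs. Another 378 (15.2%) lay outside the listed gene models, 63 (2.53%) in introns and 39 (1.57%) in 5' UTRs. Within exons, 3' UTRs held 1.10 times the number expected from their length (permutation p = 0.002) and 5' UTRs 0.252 times (p = 0.002), while coding sequence held 1.03 times (p = 0.0519). Last exons held 1549 of 1923 midpoints in transcripts with several exons (80.6%), against 57.8% expected (permutation p = 0.002). Nearly all exonic midpoints, 2029 of 2046, lay in exons at least as long as the smallest region, 350 bases. With placement kept 175 bases from transcript ends, the ratio was 0.451 in 5' UTRs (permutation p = 0.002) and 0.952 in coding sequence (permutation p = 0.00799). When placement was restricted to exons of at least 350 bases, the excess in 3' UTRs turned into a deficit at 0.817 times the expected number, coding sequence rose to 1.33 times, 5' UTRs stood at 0.342 times, and the stop codon window kept an excess at 2.25 times (permutation p = 0.002 each).

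The 3' UTR share of midpoints in coding sequence and 3' UTRs was 49.4% (505 of 1022) in genes on the + strand and 40% (394 of 985) in genes on the - strand, a difference of 9.41 percentage points (95% interval 5.08 to 13.7; Fisher exact p = 2.42e-05). With the authors' centre position in place of the midpoint the difference was -20.2 percentage points (-24.5 to -16.0). Shares of coding sequence and 3' UTR by strand thus moved with the reference point, and the ratio at the stop codon was 2.95 with the centre position.

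**Figure D2:**
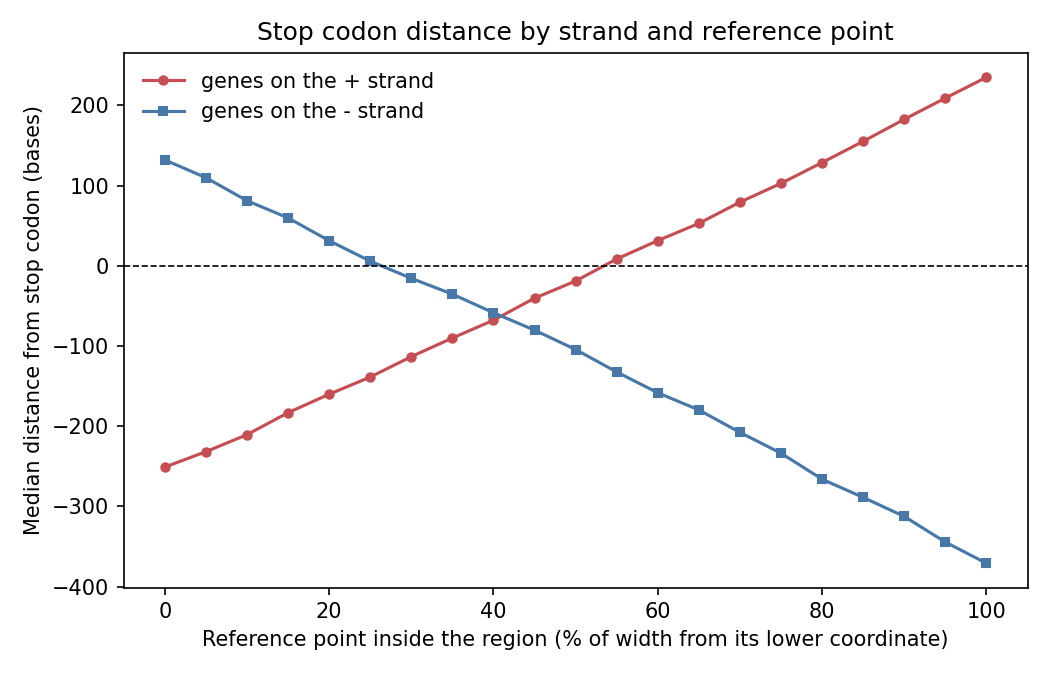
Median distance from the stop codon (vertical axis, bases) for reference points from the lower to the upper coordinate of each region (horizontal axis, percent of width), for genes on the + strand (circles) and the - strand (squares). The medians of the 2 strands nearly coincide at 40% of the width, at -67.9 and -58.6 bases, and differ at the midpoint (-19 and -104.5).

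The median log2 coverage ratio was 4.05 in 3' UTRs, 4.01 in coding sequence, 4.03 outside genes, 3.87 in 5' UTRs (39 regions) and 3.83 in introns (63 regions), and only 3' UTRs and coding sequence were tested against each other. The mean log2 coverage ratio was 4.09 ± 0.41 (SD over 899 regions) in 3' UTRs and 4.04 ± 0.42 (SD over 1108 regions) in coding sequence, a difference of 0.048 (two-sided permutation p = 0.00917, 100000 resamples). This call ended with q below 1 (0.015, permutation p = 0.48), among the 1244 regions with the higher authors' ratio (0.018) and at the centre position (0.036), and held with the authors' ratio in place of the log2 coverage ratio (0.054, permutation p = 0.0466).

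Regions outside genes lay more often downstream than upstream of the nearest listed gene. Within 1000 bases, 63 lay beyond the 3' end and 20 before the 5' end (75.9% downstream, two-sided exact binomial p = 2.43e-06). Within 10000 bases the numbers were 128 and 54 (exact p = 4.12e-08). Both tests counted each region as independent, although several regions can lie beside the same gene.

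The gene list comparison asks which kinds of gene carried regions. Potassium channel genes, which set neuronal excitability, carried them most often, in 18 of 26 members (69.2%), against 117 of 643 other listed genes (18.2%; odds ratio 10.1, Fisher exact test, adjusted exact p = 5.38e-07). Kcnh1 reached a coverage ratio of 44.5, Kcnq5 34.7 in coding sequence (chromosome 1, 21392250 to 21392699) and Kcnj4 24.5 in coding sequence (chromosome 15, 79314550 to 79315549), while Hcn2 and Kcnma1 had no region inside the gene (a region at 23.1 outside Kcnma1 carries its label). Glutamate receptor genes carried regions in 10 of 22 members (odds ratio 3.48, adjusted exact p = 0.0211). Their highest ratios were those of the kainate receptor genes, Grik5 at 38.9 (3' UTR, chromosome 7, 25795000 to 25795449) and Grik3 at 19.2, and of the metabotropic receptor gene Grm5 at 18.8. Gria1 and Grin1 had none.

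Postsynaptic scaffold and adhesion genes carried regions in 11 of 25 members (odds ratio 3.29, adjusted exact p = 0.0239), led by Shank2 at 24.2 (3' UTR, chromosome 7, 151606800 to 151607299), Dlgap2 at 23.4, Nlgn3 at 23.3 and Nlgn1 at 20.1. Dlg4 had none. Neuronal transcription factor genes carried them in 15 of 36 members (odds ratio 3.05, adjusted exact p = 0.0118), with Bcl11b at 31.7 (coding sequence, chromosome 12, 109153500 to 109153899), Neurod2 at 25.7, Zic1 at 23.1 and Bcl11a at 18.97, and none inside Tbr1 or Mef2c (a region at 19.9 outside Mef2c carries its label). Axon guidance genes carried them in 16 of 40 members (odds ratio 2.86, adjusted exact p = 0.015), with Efnb2 at 39.5, Sema3c at 30.3, Epha7 at 19.4 and Sema6d at 18.7, and none in Robo1 or Dcc. Chromatin regulator genes carried them in 15 of 39 members (odds ratio 2.66, adjusted exact p = 0.0211), with Nsd1 at 28.1, Arid1b at 28.0, Arid1a at 23.6 and Setd5 at 23.5, and none in Ezh2 or Dnmt1.

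Lower shares were called in 3 lists of housekeeping complexes. Ribosomal protein genes carried a region in 0 of 73 members (adjusted exact p = 5.38e-07), nuclear genes of oxidative phosphorylation in 0 of 48 (adjusted exact p = 0.000166) and proteasome genes in 0 of 31 (adjusted exact p = 0.00685). Rpl3, Rps6, Ndufs1, Sdha, Psma1 and Psmd1 are examples. Glycolysis genes, with Gapdh and Aldoa, had 0 of 17 members (adjusted exact p = 0.0736), choroid plexus and ependymal markers, with Ttr and Foxj1, 0 of 12 inside the gene (adjusted exact p = 0.277; a region at 30.5 outside Foxj1 carries its label) and blood markers, with Alas2, 0 of 8 (adjusted exact p = 0.533). Clock genes, with none in Per1 or Clock, had 0 of 16 by their listed symbols (adjusted exact p = 0.113), and 1 of 16 once older symbols were matched (adjusted exact p = 0.431), since Bhlhe40 stands in the table as Bhlhb2 at 23.9. None of these 4 lists passed the test.

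**Figure D3:**
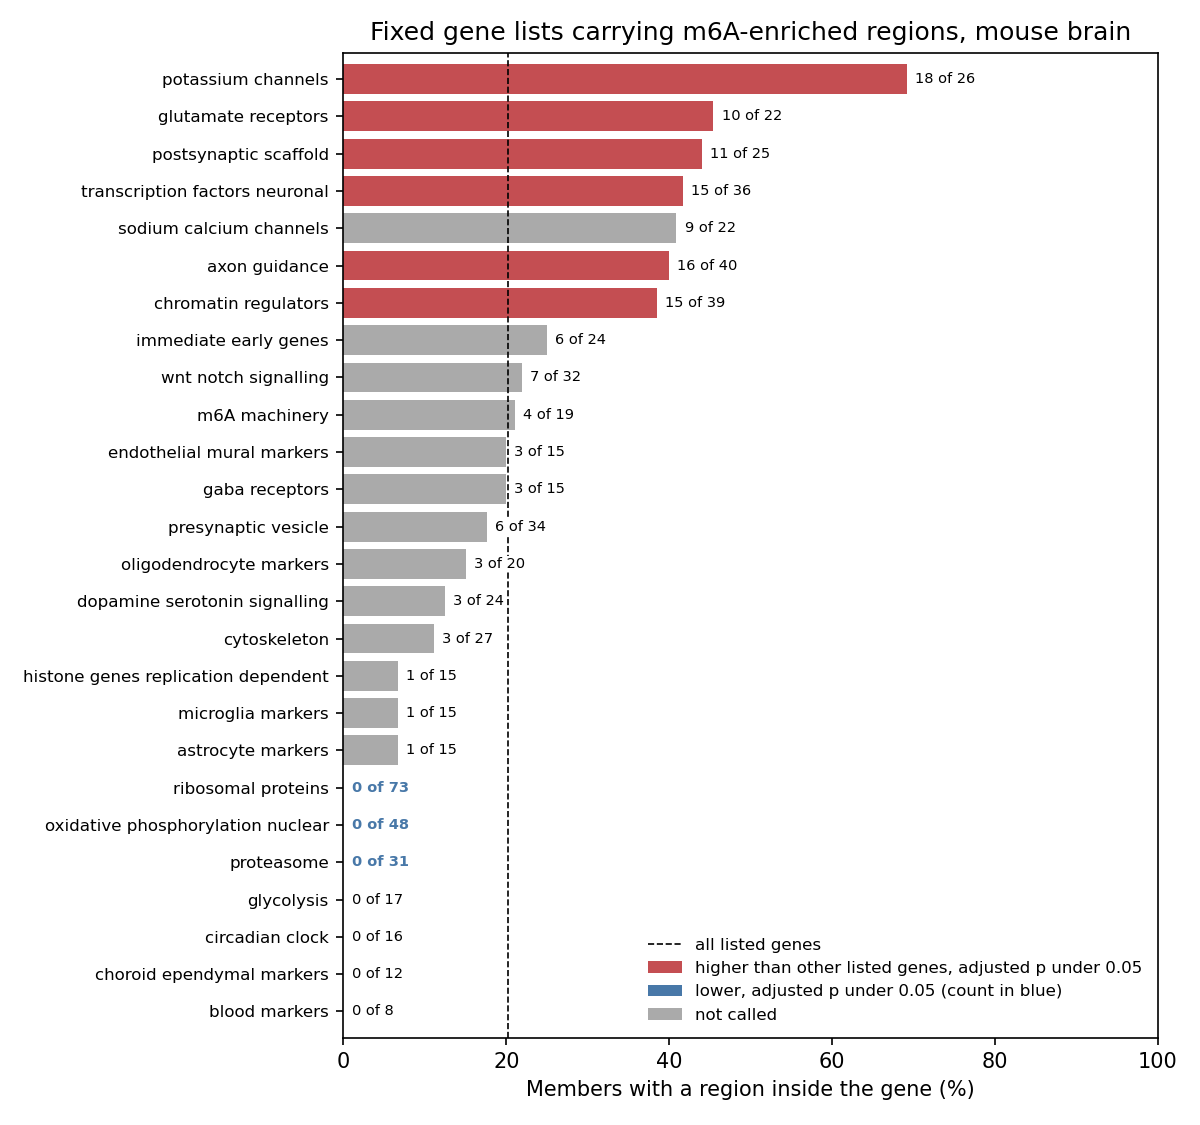
Percent of members with a region inside the gene (horizontal axis) for 26 lists fixed before the data were examined, with counts by listed symbol beside the bars. The dashed line marks all 669 listed symbols (20.2%) and colours mark called lists, from potassium channels at 69.2% to ribosomal proteins, oxidative phosphorylation and proteasome at 0.

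The enzymes and readers of m6A carried regions in 4 of 19 members (adjusted exact p = 1). With q below 1 required, 3 of 19 members kept a region. The regions given here for Rbm15 and Ythdf1 had a q of 1, so that count includes a region not given here. Ythdf2, an m6A reader gene, had a coverage ratio of 20.5 (coding sequence, chromosome 4, 131760150 to 131760549), Rbm15 18.1 (coding sequence, chromosome 3, 107133200 to 107133649), the methyltransferase adaptor gene Wtap 17.3 (3' UTR, chromosome 17, 13167500 to 13168349) and the reader gene Ythdf1 13.2 (coding sequence, chromosome 2, 180645450 to 180645849). The methyltransferase genes Mettl3 and Mettl14, the demethylase genes Fto and Alkbh5, and Cbll1, Hnrnpa2b1, Igf2bp1, Igf2bp2, Igf2bp3, Kiaa1429, Rbm15b, Ythdc1, Ythdc2, Ythdf3 and Zc3h13 had no region inside the gene under their listed symbols. A region listed under an unmatched mouse name of these genes would have been missed.

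Sodium and calcium channel genes carried regions in 9 of 22 members (adjusted exact p = 0.0673; 9.17e-05 against human symbols, 0.0132 with at least 2 regions required), with Cacna1h at 23.9, Scn1a at 21.8, Scn8a at 21.3 and Cacna2d1 at 18.4, and none in Cacna1a or Cacna1c. Presynaptic genes had 6 of 34 (adjusted exact p = 0.937), with Nrxn2 at 25.04 and Bsn at 22.3 and none in Snap25 or Syp. Immediate early genes had 6 of 24 (adjusted exact p = 0.784; 0.0281 against human symbols), with Fosl2 at 27.7 and Jun at 19.4 and none in Fos or Arc. Wnt and Notch genes had 7 of 32 (adjusted exact p = 0.937; 0.03 against human symbols), with Wnt7b at 21.9 and Apc2 at 21.8. GABA receptor genes had 3 of 15 (adjusted exact p = 1), namely Gabbr2 at 23.1, Gabra4 at 22.3 and Gabrb2 at 21.5. Dopamine and serotonin genes had 3 of 24 (adjusted exact p = 0.607), namely Htr2a at 22.8, Drd1a at 22.5 and Adcy5 at 11.3. Cytoskeleton genes had 3 of 27 (adjusted exact p = 0.501), namely Mapt, Ank2 and Ank3, and histone genes 1 of 15 (Hist1h1c, adjusted exact p = 0.501). With q below 1 required, dopamine and serotonin genes kept 2 of 24 and cytoskeleton genes 2 of 27.

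No list of cell type markers passed the test. Astrocyte markers had 1 of 15 (Sox9 at 24.9, adjusted exact p = 0.501), with none in Gfap or Aqp4. Microglia markers had 1 of 15 (Tmem119 at 18.4, adjusted exact p = 0.501), with none in Cx3cr1 or Aif1. Oligodendrocyte markers had 3 of 20 (adjusted exact p = 0.937), namely Olig1 at 26.5, Olig2 at 14.7 and Pdgfra at 13.3, with none in Mbp. Endothelial and mural markers had 3 of 15 (Pdgfrb, Cldn5 and Slc2a1, adjusted exact p = 1). With q below 1 required, oligodendrocyte markers kept 1 of 20 and endothelial and mural markers 2 of 15.

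Expression and transcript length of listed genes without a region were not analysed here, and both bear on whether a region can be found. A member whose region is listed under an unmatched mouse name also counts as without a region. The other listed genes also include the ribosomal, oxidative phosphorylation and proteasome lists (73, 48 and 31 symbols, none with a region). These lower the share that each higher list was compared with, so the higher and lower calls are not independent of each other. No test left these 3 lists out of the comparison, so whether each higher call would hold without them is not known. Genes with an exonic midpoint had a median exonic length of 3835 bases, and 23 of 1786 were under 1000 bases. Of the 6 higher lists, potassium channels alone were called among the 1244 regions with the higher authors' ratio and with q below 1 (adjusted exact p = 2.88e-07 and 7.14e-07), where the odds ratios of the other 5 lay between 1.23 and 3.04 and proteasome stayed at 0 of 31 without a call (0.151 and 0.153). Against human symbols the 6 odds ratios rose to between 7.22 (chromatin regulators) and 26.1 (potassium channels). Of the list symbols 98.5% matched this background, against 83.4% of genes with a region, which by itself raises list odds ratios. Genes not expressed in brain were not removed from it. Ribosomal proteins alone of the 3 lower lists were called (adjusted exact p = 0.0125). Oxidative phosphorylation and proteasome stayed at 0 without a call (adjusted exact p = 0.0703 and 0.271).

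Among genes with a region, no list of the 10 with at least 5 such genes differed in enrichment from random lists after adjustment (two-sided permutation test of the median), and 2 had an unadjusted p under 0.05. Potassium channel genes had a median log2 coverage ratio of 4.37 over 18 genes, against 4.08 in random lists (permutation p = 0.0166, adjusted p = 0.0828). Axon guidance genes had 3.75 over 16 genes (permutation p = 0.00778, adjusted p = 0.0778). With the mean in place of the median no list passed either. Potassium channels then had a permutation p of 0.00956 (adjusted p = 0.0956) and axon guidance genes one of 0.0552 (adjusted p = 0.276).

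Longer transcripts carried more regions. Across the 1786 genes with an exonic midpoint, the number of midpoints followed exonic length with a Spearman rho of 0.223 and a Pearson r of 0.244 (two-sided permutation p = 1e-05 for rho, the smallest that 100000 resamples can give). Median exonic length was 3632 bases in 1542 genes with 1 midpoint, 4634 in 229 genes with 2 and 8032 in 15 genes with 3 or more. Genes are not independent replicates.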

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

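The comparisons of enrichment between classes and of the side of the gene, and the tests with q below 1 or at most 0.05, with nearest-gene labels, with the human background, with older symbols and with restricted placement, were chosen after seeing the data. No paired analysis was possible because each region has 1 pooled value per group. For the same reason tests per library, leaving out libraries, and the overlap of replicates or antibodies were not run. The planned backgrounds of mouse genes and Fisher tests of pooled counts were not run either, and the caller's behaviour at other depths cannot be judged. The list of 2487 regions fell to 1244 among those with the higher authors' ratio, to 1304 with q below 1 and to 2 with q at most 0.05, by construction. The excess at stop codons stayed past its threshold under all 7 alternatives, between 2.25 and 3.21 times the expected number.

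With placement restricted to exons at least as long as the smallest region, the ratio in 3' UTRs reversed to 0.817 and that in coding sequence rose to 1.33. Keeping placements 175 bases from transcript ends turned the coding ratio to 0.952. The causes of both were the bases allowed in the draw. The difference in log2 coverage ratio between 3' UTRs and coding sequence lost its threshold with q below 1 (0.015), among those 1244 regions (0.018) and at the centre position (0.036); the cause was not tested. Of 6 higher lists, 1 was called among the 1244 regions, 1 with q below 1, 3 with nearest-gene labels and 3 with at least 2 regions required (2 of the 6, and sodium and calcium channels). With nearest-gene labels, glutamate receptors, postsynaptic scaffold and chromatin regulators kept odds ratios of 2.94, 2.78 and 2.23 (adjusted exact p = 0.0507, 0.0507 and 0.0704). The lower lists, 3 before, numbered 0 with at least 2 regions and 1 against the human background, where all 6 higher lists stayed among 9 (with sodium and calcium channels, immediate early genes, and Wnt and Notch), and 2 among the 1244 regions and with q below 1, where the proteasome call ended. With only 24 listed genes carrying 2 regions, a list at 0 could hardly be called lower (0 of 73 gave an unadjusted exact p of 0.0967), so that 0 says nothing about the lower lists. Matching older symbols kept all 6 and 3 calls. Requiring 2 regions reversed the odds ratio of glutamate receptors to 0, of neuronal transcription factors to 0 and of axon guidance to 0.676, since few genes carry 2. Among named lists, 30 odds ratios kept their call and 21 others lost it in the same direction.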

Other observations

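The patterns below, apart from the stop codon excess that the series title names, were first seen in these data, and the Zfp test, the internal-exon and gene-model tests of the strand difference (the latter with its bound) and the long-exon test limited to exons that can hold a region were chosen after related results had been seen. Zinc finger genes with Zfp symbols formed a large family among genes with a region, with 81 genes and 103 regions inside them, and 21 carried at least 2. Of their 100 exonic midpoints, 68 lay in coding sequence (68.0%), against 51.2% under random placement in the same transcripts (95% range 42.98 to 59.0%) and 53.4% (1040 of 1946) in other genes (Fisher exact p = 0.00524). Placement only in exons of at least 350 bases was not run for this family. Over all genes it gave 1.33 times the expected number in coding sequence, so the Zfp share was not separated from exon length. The Fisher test counted midpoints of the same gene as independent. Protocadherin genes, whose products are neuronal adhesion proteins, carried 17 regions in 16 genes, and all 17 lay in coding sequence. Over all genes 54.2% of exonic midpoints did, and no share expected from the protocadherin transcripts was computed. The 16 genes included Pcdh17, Pcdh9, Pcdh20 and members of the Pcdhb and Pcdhg clusters, whose similar copies can share reads. Solute carrier genes carried 26 regions in 23 genes (11 in coding sequence, 12 in 3' UTRs), among them the neuronal chloride transporter gene Slc12a5. Olfactory receptor and keratin genes carried none inside a gene. Genes with a single exon numbered 110 among those with an exonic midpoint.

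Regions outside genes included a few that held much of the coverage. A region of 38600 bases at chromosome 9, 2999950 to 3038549, whose nearest listed gene is Alkbh8, held a MeRIP coverage of 548585 and 19.5% of the sum over all regions (19.1% in control), at a ratio of 16.4. Regions labelled Sfi1 began at the same coordinate on chromosome 11, with 5 of 8 outside the gene. Of 12 regions labelled Mid1, 10 lay outside it between 166428700 and 166446249 on X. MeRIP coverage summed to only 5266 over all Sfi1 regions and 7596 over all Mid1 regions. A region labelled Tmem125 and outside it (chromosome 4, 118219600 to 118221549) had a MeRIP coverage of 73771 at a ratio of 31.9. The 2 regions outside Lrrc4c on chromosome 2, at 98502900 and 98503700, had MeRIP coverages of 47286 and 9560. The single mitochondrial region (12900 to 13249), for which no gene model is listed, had 79462 at a ratio of 10.1. On chromosome 12, 4 regions labelled Rtl1 lay outside it between 110796850 and 110899399, with ratios of 12.5 to 31.3. These regions were named after their values were seen. Whether coverage is summed over the width of a region or given per base is not stated. Coverages of regions of unlike width are therefore not directly comparable.

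No biological explanation was tested for these patterns, since the table compares no biological groups. Midpoints within 200 bases of the stop codon were weighed against 3 technical explanations, and the tables argue against each as the whole cause. In genes with a 3' UTR of at least 1000 bases, 25 midpoints lay 300 to 500 bases before the transcript end and 245 in the first 200 bases after the stop codon, a ratio of 0.102 (upper 95% limit 0.154) where coverage rising toward the end would need 1 or more. The 1244 regions with the higher authors' ratio held 3.18 times the expected number, so weak regions do not account for it. Within last exons alone the ratio was 2.10 (661 against 315, permutation p = 0.002), so the place of the stop codon in the last exon may explain part of the excess and not all of it.

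For the strand difference in 3' UTR share, a candidate explanation is a shift of the listed coordinates along the chromosome. For 295 midpoints in internal exons over 400 bases (coding or UTR), a landmark without a stop codon, the position was a median of 56.5 bases above the exon centre (95% bootstrap interval 29.5 to 82.5), close to the 42.8 bases per strand that the stop codon distances give. The offset was 118 bases on the + strand (81.5 to 171) and 25.5 on the - strand (-17.5 to 49.0), so the interval on the - strand includes 0. A shift alone would give the same offset on both strands, and these intervals do not overlap. The values therefore argue against a shift as the whole cause. Random placement in the same gene models gave a strand difference of 1.10 percentage points (upper limit of the draws 5.18) against 9.41 observed, so gene models do not account for all of it.

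Coding midpoints lay in long exons, with a median of 2052 bases for the exon hit in 1035 midpoints, against 1333 for random placement over coding bases (upper limit 1433). Length in proportion therefore does not account for it. Regions of at least 350 bases may need exons that can hold them. Placement only in exons of that length raised the expected median to 1916 (upper limit 1975), against 2094 observed in 1020 midpoints. A limit of 350 bases alone could thus account for part of the excess and not all of it. Wider regions were given no longer limit, and the gathering at stop codons and in last exons was not removed. What remains was therefore not separated from region width or from that gathering. Among the 280 coding midpoints in internal exons of any length, the median exon was 1029 bases against 596 expected. That expectation had no limit on exon length, while 271 of the 280 midpoints lay in exons over 400 bases. It therefore cannot show an excess beyond the limit set by region width.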
